A study of Homo sapiens with 12 samples.

How the data were processed

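RNA sequencing of COLO-357 cells in 4 groups of 3 libraries was deposited as one table of RPKM values, with one value per gene symbol and library and no column for any other sample. Per the file headers each column is a library named as in the labels. RPKM (reads per kilobase of gene, scaled to the mapped reads of the library) was computed by the authors, and the submitters' processing notes name STAR, Partek and the genome build hg38, without versions, roles or the gene annotation. Values far below a single read beside exact zeros are what a model-based split of reads between overlapping or similar genes leaves, so genes with close copies carry uncertain values. The labels' protocols give DMEM with 10% serum, lentiviral infection and total RNA, and state neither which shRNA sequences were used nor the strand.

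The deposited RPKM values were used without rescaling. Genes were tested where RPKM was at least 1 in at least 3 of the 12 libraries, which kept 12506 of 22954. Tests used limma 3.58.1 in R 4.3.3 on log2(RPKM + 1), with one fit of the 4 group means over all 12 libraries, a mean-variance trend, two-sided tests and Benjamini-Hochberg adjustment per contrast at 0.05. The contrasts were each silenced group against shNS, the co-silenced group against each single group, shp15 against shp16, and the interaction (co-silenced minus shp15, minus shp16, plus shNS). Figures were drawn in Python 3.11.15 with matplotlib 3.10.9. Because the table holds no counts, no count model was fitted. Relative depth was recovered from the ratios of the smallest steps between libraries. The absolute depth came from small nucleolar RNA genes, of which 178 of 216 lay within 1% of a common step with RefSeq lengths, and it is an estimate of aligned reads. A gene was taken to have no close copy where under 10% of its 31-base words occurred in GENCODE release 29 transcripts of other genes. Symbols were matched to RefSeq for 12163 of the 12506 tested genes, and positions come from GENCODE release 29 on GRCh38, where 262 of 273 named genes were found.

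Before the data were examined, 33 gene lists were written, of which 28 had at least 5 tested genes. They cover CDK inhibitors, cyclins and RB family genes, DNA replication, mitosis, p53 targets, interferon response, class I antigen presentation, NF-kB targets, TGF-beta response, epithelial junctions, mesenchymal genes, integrins and invasion, classical and basal-like pancreatic cancer subtypes, glycolysis, respiratory chain, cholesterol, fatty acid synthesis, hypoxia, unfolded protein response, heat shock and immediate early genes, ERK output, YAP and Wnt targets, ribosome biogenesis, ribosomal proteins, histones, lysosome and autophagy, and hepatocyte markers. Acinar, fibroblast, leukocyte and endothelial markers and mitochondrially encoded mRNAs had fewer than 5 tested genes. Lists were tested with camera at a preset correlation of 0.01, adjusted over 112 tests (28 lists in 4 contrasts), beside camera with an estimated correlation and fry, which tests whether the members of a list move one way on balance and does not compare a list with other genes. The genes named were fixed by rule: the targeted genes, the 8 largest rises and 8 largest falls among genes past the threshold whose groups did not overlap in each comparison with shNS, 5 and 5 in the other comparisons, without clone names, antisense and small RNA genes, and up to 4 members of each list. Non-overlap of 3 libraries with 3 arises by chance in 10% of genes. For the interaction, 100 data sets were compared, the real one and others that kept the single changes with no departure and the residuals of the group means shuffled over the libraries.

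Simulated data were drawn from the mean of each of the 12506 tested genes over all libraries and its spread pooled over the groups, with 200 genes changed. The test recovered 30, 92, 100, 100% of genes changed 1.2, 1.5, 2 and 4-fold for shp15 against shNS, 24, 90, 96, 100% for shp16 and 28, 92, 100, 100% for co-silencing. False calls were 3.01%, 4.91% and 6.43% of the calls. The draws differ only at random and in the group shifted. Far fewer genes were changed in them than were called in the data, so these shares may not carry over. Alternatives fixed beforehand were a pseudocount of 0.1, no filter, a mean RPKM of at least 5, median-of-ratios scaling, quantile normalization, only the groups compared, a replicate block, no variance trend, and leaving out each library. Chosen after seeing the data were leaving out shNS replicate 2 and shp16 replicate 3, a JCHAIN covariate, leaving out annotated pseudogenes, and a list of 18 plasma cell markers.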

Results

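Gene expression was measured by RNA sequencing in COLO-357, an established human line from a metastatic pancreatic ductal adenocarcinoma. The study asks how CDKN2A and CDKN2B, neighbouring tumour suppressor genes that encode the CDK4 and CDK6 inhibitors p16 and p15, bear on spread to the liver. There were 4 groups of 3 libraries: a non-silencing control (shNS), cells with an shRNA against CDKN2B (shp15), cells with one against CDKN2A (shp16), and cells in which both were targeted (shp15_shp16, called co-silenced here). The study's description has 3 replicates of each silenced line seeded 24 hours before RNA extraction. It does not say whether they came from separate passages, and their spread does not cover differences between independently made lines. The table held RPKM values for 22954 gene symbols, of which 12506 reached 1 RPKM in at least 3 of the 12 libraries and were tested. The steps between low values put the depth, in 1e+06 reads, at 17.5, 21.01, 16.8 in the shNS libraries, 13.6, 14.5, 13.01 in those labelled shp15, 14.6, 19.1, 21.1 in shp16 and 22.97, 20.1, 19.6 in the co-silenced libraries. At those depths a 1 kb gene at 1 RPKM rests on about 13.01 to 22.97 reads. Values below are RPKM means ± SD (n = 3 libraries) and log2 fold changes of RPKM + 1.

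CDKN2A (chromosome 9, 21967753 to 21995301, GRCh38, minus strand) fell in both groups that received an shRNA against it, and CDKN2B (chromosome 9, 22002903 to 22009363, minus strand) was lower in the co-silenced libraries alone. CDKN2A averaged 33.6 ± 3.77 in shNS, 2.62 ± 0.480 in shp16 and 4.43 ± 0.725 in the co-silenced libraries. Those means are 12.8-fold and 7.58-fold lower than in shNS (log2 fold changes -3.26 and -2.67, limma adjusted p = 1.13e-10 and 1.60e-09). CDKN2B averaged 3.76 ± 0.04997 in shNS, 3.81 ± 0.397 in shp16 and 2.51 ± 0.148 in the co-silenced libraries, where it fell (log2 fold change -0.44, limma adjusted p = 1.69e-04). In the libraries labelled shp15, CDKN2B stood at 3.91 ± 0.265 and was not lower than in shNS (log2 fold change 0.045, 95% interval -0.10 to 0.19, limma adjusted p = 0.601). The targeted transcript therefore does not bear out that label, and every direction given for the libraries labelled shp15 carries this limit. CDKN2A in those libraries was 27.0 ± 0.988 (log2 fold change -0.30, limma adjusted p = 0.0388), a call lost in 10 of 17 alternatives (adjusted p from 0.00559 to 0.162). Those include the omission of shNS replicate 1 or 3 or of any library labelled shp15, and its log2 fold change was -0.22 without shNS replicate 3. An exact two-sided permutation test of 3 libraries against 3 cannot go below p = 0.1, which is what it gave for the falls of CDKN2A and CDKN2B. Values per gene symbol do not separate the p16 and ARF transcripts of CDKN2A.

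**Figure D1:**
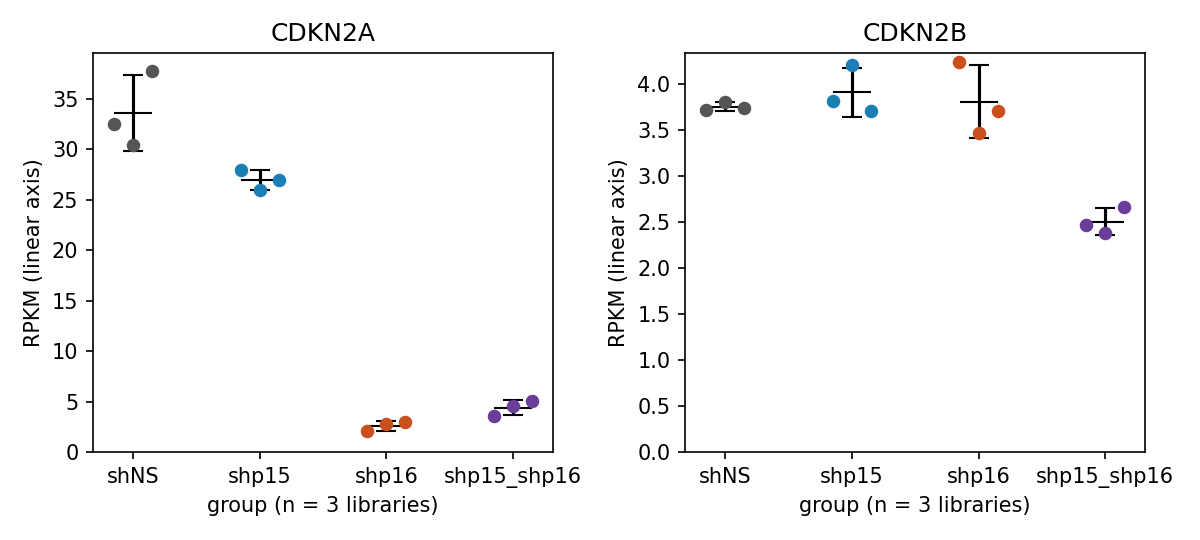
RPKM of CDKN2A (left) and CDKN2B (right) in each library, with points for the 3 libraries of each group and bars for the mean ± SD, on linear axes that start at 0. CDKN2A drops from 33.6 in shNS to 2.62 in shp16, and CDKN2B is lower in the co-silenced group, at 2.51, but not in the group labelled shp15.

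Libraries grouped by label. The number after S in their titles ran in blocks by group in the silenced groups and was spread in shNS. For the silenced groups, grouping by label cannot be told apart from grouping by that number. The first 2 principal components held 46.9% and 31.1% of the variance of the tested genes. The shp16 and co-silenced libraries lay on one side of the first, the libraries labelled shp15 lay on the other, and shNS stood apart on the second. Pearson correlations across genes, which are not independent replicates, were 0.988 to 0.997 within groups and 0.938 to 0.982 between them. One set of genes was read in the libraries labelled shp15 and hardly anywhere else: 28 genes, 19 of them protein-coding, were above 5 RPKM in all 3 of these libraries and below 0.5 RPKM in the other 9. They included RPL10L, a testis-expressed copy of RPL10, at 109.7 ± 5.84, and ACTG2, a smooth muscle actin, at 53.3 ± 1.09. TM4SF4, a tetraspanin-like membrane protein, was 114 ± 3.53 there and at most 0.597 in any other library. Of 215 tested pseudogenes, 58 rose at least 2-fold there, against 3 in shp16 and 1 in the co-silenced libraries. A second set, plasma cell genes, followed single libraries: JCHAIN, the joining chain of secreted antibodies, was 7.40 in shNS replicate 2, 20.4 in shp16 replicate 3 and 14.6 to 27.2 in the co-silenced libraries, and at most 0.514 in the remaining 7. A list of 18 plasma cell markers was written after the data had been seen, 10 of them after their own values. ITGB7 reached 20.0, IGLL5 10.3 and MZB1 6.96 in co-silenced replicate 3, while SDC1 (133 in shNS replicate 1) and XBP1 (56.2) are also expressed by epithelial cells. Of the 8 markers whose own values had not been seen, SLAMF7 was 0.243 in shNS replicate 2, 0.339 in shp16 replicate 3, 0.355 to 0.523 in the co-silenced libraries and at most 0.0751 in the others, and DERL3 reached at most 0.195. FCRL5, TNFRSF13B and CD27 did not exceed 0.330 in any library, and PIM2, PRDM1 and FKBP11 were read in all 12.

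**Figure D2:**
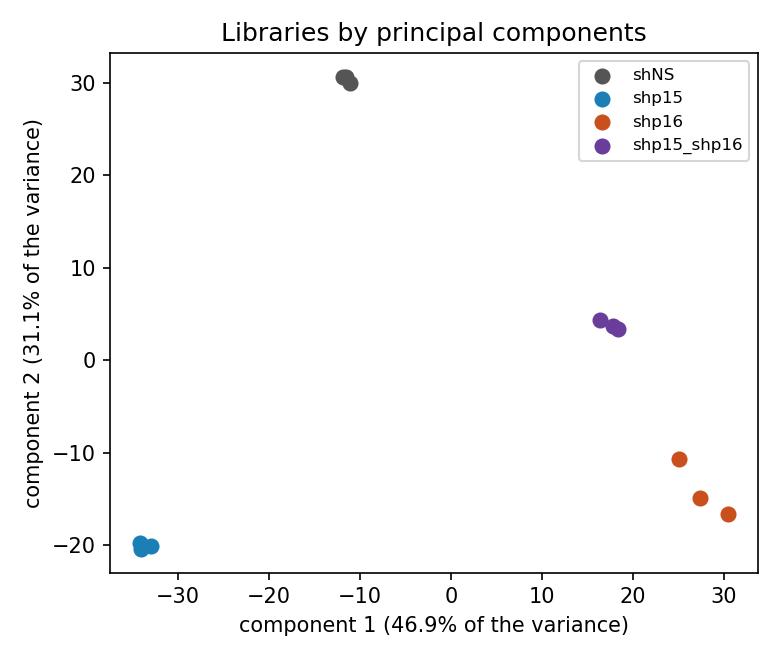
Positions of the 12 libraries on the first 2 principal components of the tested genes (log2 of RPKM + 1, arbitrary units), coloured by group. The axes hold 46.9% and 31.1% of the variance, and the 3 libraries of each group lie together.

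**Figure D3:**
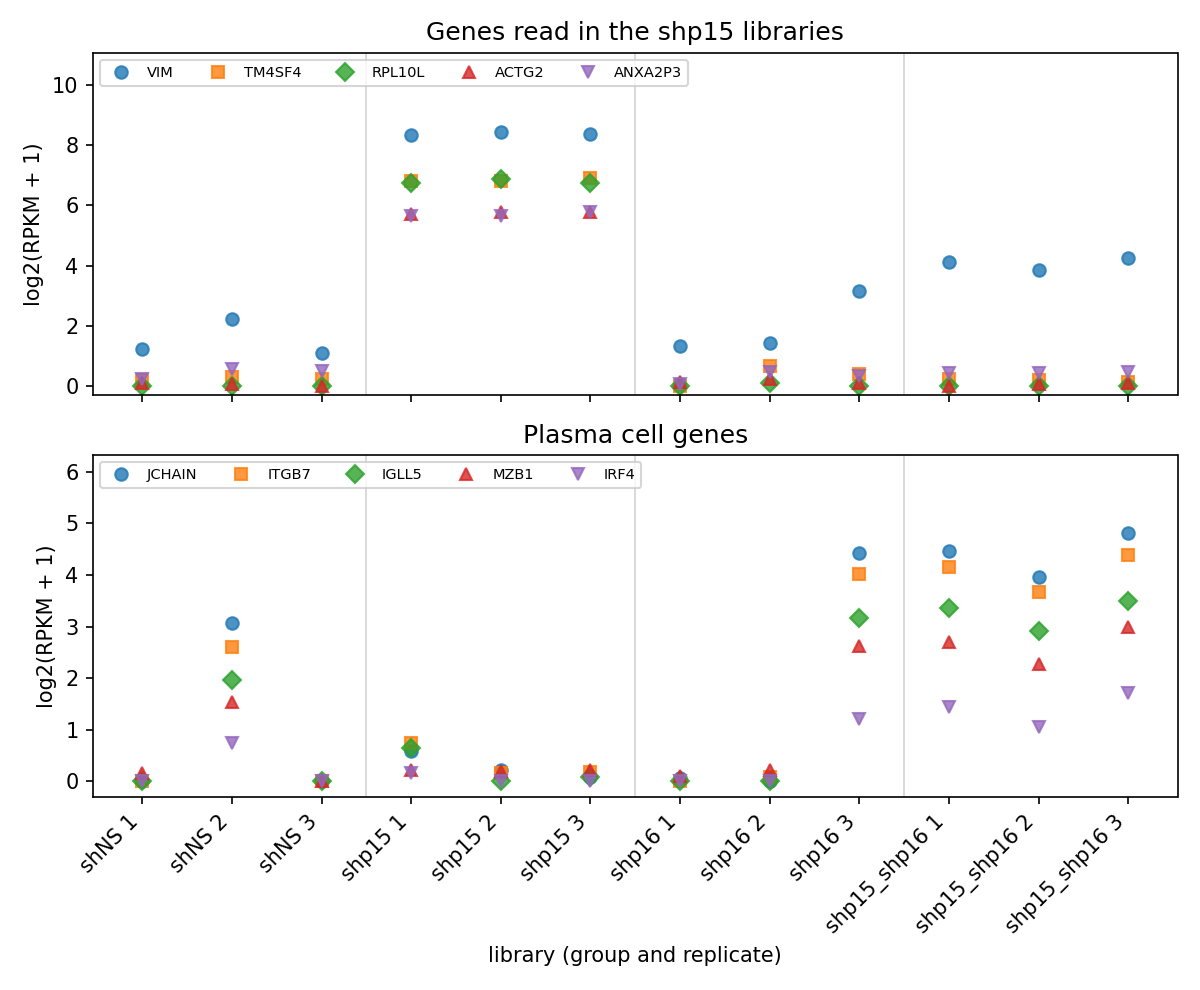
Log2 of RPKM + 1 in each of the 12 libraries for 5 genes read in the libraries labelled shp15 (top) and 5 plasma cell genes (bottom). JCHAIN reaches 7.40 RPKM in shNS replicate 2 and 20.4 RPKM in shp16 replicate 3, and VIM reaches 345 RPKM in shp15 replicate 2.

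With CDKN2A alone silenced (shp16 against shNS), the largest rises and falls were in the following genes. ALPG, a germ cell alkaline phosphatase, rose from 4.63 ± 0.399 to 435 ± 27.0, and LXN, which encodes the carboxypeptidase inhibitor latexin, from 13.6 ± 0.747 to 687 ± 27.4. CEACAM5, the carcinoembryonic antigen, went from 0.889 ± 0.124 to 53.8 ± 2.25, and CES1, a carboxylesterase, from 0.539 ± 0.118 to 54.6 ± 4.08. CALCA, the precursor gene of calcitonin and CGRP, fell from 75.1 ± 1.51 to 3.05 ± 0.696, and S100A2, a calcium-binding protein of basal epithelia, from 67.5 ± 4.06 to 2.79 ± 0.209. The other large rises were CGA, the shared alpha subunit of glycoprotein hormones (log2 fold change 4.47), MUCL3 (4.45), CEACAM7 (4.29) and RTN4RL2 (4.15). Large falls were also seen for SYT8 (-3.55), TNNI2 (-3.42), the growth factor BMP7 (-3.30), RASSF10 (-2.69) and PTK7 (-2.67). In all, 3627 genes rose and 3982 fell among the 12506 tested (limma, Benjamini-Hochberg adjusted p under 0.05), of which 1263 rose and 756 fell by at least 1.5-fold. The groups did not overlap in 63.4% of tested genes, where chance gives 10%.

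NF-kB target cytokines and chemokines were the group whose call held with both correlation settings. Of 16 members, 14 rose, 1 fell and 1 did not pass (14 and 1 adjusted over the list alone, camera adjusted p = 4.26e-08, adjusted p = 0.0218 with an estimated correlation). Among those that rose were the neutrophil chemokine CXCL8 (1.58 to 18.8), RELB (1.11 to 7.52) and IL6 (0.344 to 4.34). Of 18 genes of the classical pancreatic cancer subtype, 14 rose, 2 fell and 2 did not pass (14 and 2 adjusted over the list alone, camera adjusted p = 3.84e-06, adjusted p = 0.142 with an estimated correlation). TFF1, a mucosal trefoil peptide, averaged 5.22 in shNS and 109 in shp16, and AGR2 10.9 and 82.2. Of 20 basal-like subtype genes, 7 rose, 11 fell and 2 did not pass (7 and 11 adjusted over the list alone, camera adjusted p = 0.127, adjusted p = 0.473 with an estimated correlation), so the list as a whole did not pass, although KRT5 (-2.67) and TP63, a basal cell transcription factor (-2.42), fell. Of 15 genes of MHC class I presentation, 14 rose, 1 fell and 0 did not pass (14 and 1 adjusted over the list alone, camera adjusted p = 4.02e-05, adjusted p = 0.1999 with an estimated correlation). HLA-B rose from 53.4 to 221. Of 27 interferon response genes, 16 rose, 6 fell and 5 did not pass (16 and 6 adjusted over the list alone, camera adjusted p = 0.0131, adjusted p = 0.151 with an estimated correlation). OASL had a log2 fold change of 2.39 and IFI27 of 2.33.

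The mitosis and DNA replication lists passed downward with the preset correlation and not with the estimated one. Of 40 mitosis genes, 1 rose, 31 fell and 8 did not pass (1 and 32 adjusted over the list alone, camera adjusted p = 1.67e-06, adjusted p = 0.231 with an estimated correlation). ASPM, a spindle pole protein, had a log2 fold change of -1.10 and CENPF of -1.06. Of 44 DNA replication genes, 2 rose, 17 fell and 25 did not pass (1 and 15 adjusted over the list alone, camera adjusted p = 0.0415, adjusted p = 0.512 with an estimated correlation), a call also lost without shNS replicate 2 and without shp16 replicate 1 (adjusted p = 0.0664 and 0.103, range 4.46e-04 to 0.512 over the alternatives). Of 28 ribosome biogenesis genes, 0 rose, 19 fell and 9 did not pass (0 and 19 adjusted over the list alone, camera adjusted p = 0.00197, adjusted p = 0.439 with an estimated correlation). Of 45 ribosomal protein genes, 34 rose, 0 fell and 11 did not pass (34 and 0 adjusted over the list alone, camera adjusted p = 7.95e-07, adjusted p = 0.537 with an estimated correlation). Reads of ribosomal protein genes such as RPL7 (1.08) are shared with their pseudogenes, so single values are uncertain. Of 22 YAP target genes, 2 rose, 12 fell and 8 did not pass (2 and 12 adjusted over the list alone, camera adjusted p = 0.0191, adjusted p = 0.428 with an estimated correlation), a call also lost without shp16 replicate 2 (adjusted p = 0.0678, range 1.15e-05 to 0.428 over the alternatives). The receptor kinase AXL had a log2 fold change of -2.11.

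Several stress and metabolic lists passed upward with the preset correlation and none with the estimated one. The fatty acid list did not pass (8 rose and 8 fell of 23, camera adjusted p = 0.940). Of 23 hypoxia-inducible genes, 18 rose, 3 fell and 2 did not pass (18 and 3 adjusted over the list alone, camera adjusted p = 0.00156, adjusted p = 0.564 with an estimated correlation). NDRG1 rose from 16.0 to 117. Of 30 unfolded protein response genes, 22 rose, 6 fell and 2 did not pass (22 and 6 adjusted over the list alone, camera adjusted p = 0.00215, adjusted p = 0.175 with an estimated correlation). CHAC1 had a log2 fold change of 3.01. Of 25 glycolysis genes, 17 rose, 4 fell and 4 did not pass (18 and 4 adjusted over the list alone, camera adjusted p = 0.00854, adjusted p = 0.537 with an estimated correlation), a call also lost under quantile normalization (adjusted p = 0.124, range 4.46e-04 to 0.537 over the alternatives). Of 25 cholesterol synthesis and uptake genes, 15 rose, 2 fell and 8 did not pass (15 and 3 adjusted over the list alone, camera adjusted p = 0.0126, adjusted p = 0.189 with an estimated correlation). Of 25 heat shock and immediate early genes, 14 rose, 4 fell and 7 did not pass (14 and 4 adjusted over the list alone, camera adjusted p = 0.0183, adjusted p = 0.405 with an estimated correlation). FOS had a log2 fold change of 2.51. Of 20 ERK output genes, 10 rose, 3 fell and 7 did not pass (10 and 3 adjusted over the list alone, camera adjusted p = 0.0236, adjusted p = 0.186 with an estimated correlation). DUSP5, an ERK phosphatase, had a log2 fold change of 2.62. Of 25 lysosome and autophagy genes, 15 rose, 2 fell and 8 did not pass (15 and 2 adjusted over the list alone, camera adjusted p = 0.0170, adjusted p = 0.426 with an estimated correlation). Of 46 respiratory chain genes, 17 rose, 2 fell and 27 did not pass (17 and 2 adjusted over the list alone, camera adjusted p = 0.0155, adjusted p = 0.711 with an estimated correlation), a call also lost under quantile normalization and without shp16 replicate 2 (adjusted p = 0.135 and 0.201, range 0.00101 to 0.711 over the alternatives). The plasma cell genes of shp16 replicate 3 stood in 1 of the 3 shp16 libraries.

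**Figure D4:**
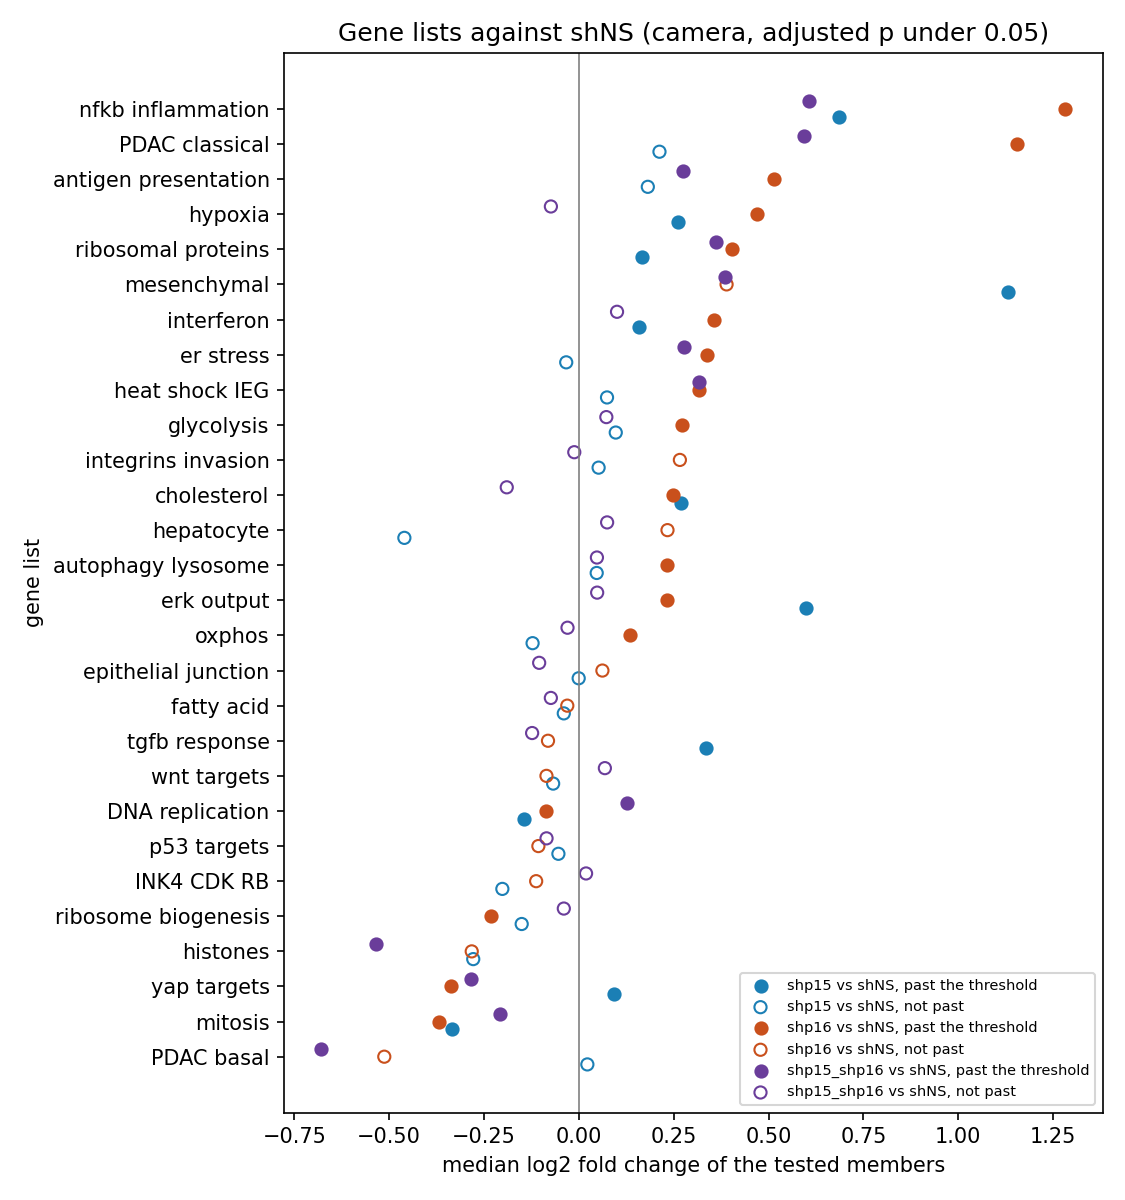
Median log2 fold change of the tested members of each of 28 gene lists in the 3 comparisons with shNS, filled where camera gave an adjusted p under 0.05 with the preset correlation and open where it did not. The NF-kB list lies at 1.28 in shp16, 0.69 in the libraries labelled shp15 and 0.61 in the co-silenced libraries.

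In the libraries labelled shp15, in which CDKN2B was not lower, 7 of the 8 largest rises named by the rule were of genes below 0.5 RPKM on average in shNS, the exception being VIM. VIM, the intermediate filament of mesenchymal cells, rose from 2.03 ± 1.38 to 334 ± 12.2, RPL10L was listed at 0 in shNS and at 109.7 ± 5.84 here, and ACTG2 rose from 0.0360 ± 0.0383 to 53.3 ± 1.09. TUBA1A, an alpha tubulin (54.1), the neuronal surface protein gene NRN1 (41.7), ANXA2P3, a processed copy of annexin A2 (50.8), and MTRNR2L10, a nuclear copy of mitochondrial 16S RNA (30.1), were also below 0.5 RPKM on average in the other groups. ACTG2, TUBA1A, ANXA2P3 and MTRNR2L10 have close copies in the genome, so their single values are uncertain. Falls were smaller: CALCA went from 75.1 ± 1.51 to 10.6 ± 0.829, TGM2, a transglutaminase, from 11.3 ± 0.440 to 1.49 ± 0.0738, and IGFL1 from 7.25 ± 0.887 to 0.793 ± 0.380. CALCB (-1.73), the activin-binding protein gene FST (-1.34), the insulin gene activator MAFA (-1.31), the ligand gene WNT10A (-1.29) and the folate receptor gene FOLR1 (-1.26) fell as well. In all, 3022 genes rose and 3840 fell among the 12506 tested (limma, Benjamini-Hochberg adjusted p under 0.05), of which 1007 rose and 284 fell by at least 1.5-fold. The groups did not overlap in 68.2% of tested genes, where chance gives 10%.

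Groups that held with both correlation settings were ERK output, mesenchymal and NF-kB genes. Of 20 ERK output genes, 18 rose, 0 fell and 2 did not pass (18 and 0 adjusted over the list alone, camera adjusted p = 2.24e-08, adjusted p = 0.0122 with an estimated correlation). The phosphatase DUSP6 averaged 2.19 in shNS and 13.5 here, and SPRY2 0.605 and 3.78. Of 19 mesenchymal genes, 14 rose, 1 fell and 4 did not pass (15 and 1 adjusted over the list alone, camera adjusted p = 2.28e-07, adjusted p = 0.0122 with an estimated correlation). Fibronectin FN1 rose from 2.03 to 19.1 and TWIST1 from 0.914 to 7.47. Of 16 NF-kB targets, 13 rose, 0 fell and 3 did not pass (13 and 0 adjusted over the list alone, camera adjusted p = 2.21e-06, adjusted p = 0.0409 with an estimated correlation). CXCL6 averaged 0.326 and 10.2. Of the members that rose, 1 ERK output, 2 mesenchymal and 3 NF-kB genes were below 0.5 RPKM on average in shNS. Both tested leukocyte markers rose in these libraries too, CD14 to 4.30 from a mean of at most 0.0819 in the other groups and CD68 from 13.2 to 21.9 (21.8 in shp16). The rises of these lists were not separated from reads of another source. Without the annotated pseudogenes 6716 genes changed, a setting chosen after seeing the data.

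Other groups passed with the preset correlation and not with the estimated one. Of 25 cholesterol genes, 18 rose, 1 fell and 6 did not pass (18 and 1 adjusted over the list alone, camera adjusted p = 3.24e-05, adjusted p = 0.0649 with an estimated correlation). HMGCS1 had a log2 fold change of 0.83. Of 22 TGF-beta response genes, 12 rose, 3 fell and 7 did not pass (12 and 3 adjusted over the list alone, camera adjusted p = 0.00156, adjusted p = 0.0677 with an estimated correlation). ID2 had a log2 fold change of 2.00. Of 22 YAP targets, 9 rose, 3 fell and 10 did not pass (9 and 3 adjusted over the list alone, camera adjusted p = 0.0279, adjusted p = 0.444 with an estimated correlation). CCN2 had a log2 fold change of 2.85. ANKRD1, a YAP target singled out after its values were seen, was among the 28 genes read in these libraries alone. Of 23 hypoxia genes, 14 rose, 1 fell and 8 did not pass (14 and 1 adjusted over the list alone, camera adjusted p = 0.00370, adjusted p = 0.588 with an estimated correlation). Of 27 interferon genes, 12 rose, 2 fell and 13 did not pass (12 and 2 adjusted over the list alone, camera adjusted p = 0.0236, adjusted p = 0.186 with an estimated correlation). Of 45 ribosomal protein genes, 17 rose, 3 fell and 25 did not pass (11 and 2 adjusted over the list alone, camera adjusted p = 0.0236, adjusted p = 0.771 with an estimated correlation), a call also lost with fry, without shNS replicate 1 and without shp15 replicate 3 (adjusted p = 0.170, 0.0630 and 0.0744, range 0.00679 to 0.771 over the alternatives). Passing downward were the division lists: of 40 mitosis genes, 0 rose, 30 fell and 10 did not pass (0 and 32 adjusted over the list alone, camera adjusted p = 9.40e-07, adjusted p = 0.231 with an estimated correlation). Of 44 DNA replication genes, 3 rose, 24 fell and 17 did not pass (3 and 25 adjusted over the list alone, camera adjusted p = 0.00370, adjusted p = 0.404 with an estimated correlation). CENPF fell to 20.4 from 37.2. The classical subtype list did not pass: of 18 genes, 9 rose, 3 fell and 6 did not pass (9 and 3 adjusted over the list alone, camera adjusted p = 0.0534, adjusted p = 0.487 with an estimated correlation). It did pass without shNS replicate 3 or shp15 replicate 3 (adjusted p = 0.0392 and 0.0417) and in 3 other settings, a pseudocount of 0.1, shNS replicate 2 and shp16 replicate 3 left out (chosen after seeing the data), and fry, which asks another question. Over its alternatives the adjusted p lay between 1.26e-04 with fry and 0.487 with an estimated correlation in camera. GATA6, a transcription factor of that subtype, rose from 2.06 to 4.99.

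With both genes targeted (shp15_shp16 against shNS), ALPG, CGA, LXN and CES1 were again among the largest rises, and the keratin genes KRT5, KRT6A and KRT13 were among the largest falls. ALPG rose from 4.63 ± 0.399 to 292 ± 4.48, CGA from 1.75 ± 0.135 to 80.4 ± 1.76 and LXN from 13.6 ± 0.747 to 366 ± 7.79. KRT5, a basal keratin, fell from 87.7 ± 0.446 to 4.70 ± 0.420, KRT13 from 38.0 ± 0.843 to 7.29 ± 0.282 and S100A2 from 67.5 ± 4.06 to 5.34 ± 0.790. HLA-DMB, which helps load peptides on MHC class II, rose from 0.240 ± 0.103 to 23.5 ± 1.06. CES1 (4.68), the protease inhibitor gene SPINK6 (3.67) and vitronectin VTN (3.39) rose as well, and MAFA (-2.60), IGFL1 (-2.59), the long non-coding RNA CERNA2 (-2.30) and KRT6A (-2.25) fell. JCHAIN was among the largest rises (3.39, limma adjusted p = 0.0142), and its call was lost without shNS replicate 1 and without shNS replicate 3 (adjusted p = 0.0602 and 0.0600, range 3.40e-08 to 0.0602 over the alternatives). In all, 2985 genes rose and 3337 fell among the 12506 tested (limma, Benjamini-Hochberg adjusted p under 0.05), of which 754 rose and 572 fell by at least 1.5-fold. The groups did not overlap in 64.0% of tested genes, where chance gives 10%.

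No list passed with an estimated correlation in this comparison, and 12 passed with the preset one. Of 20 basal-like subtype genes, 2 rose, 13 fell and 5 did not pass (2 and 14 adjusted over the list alone, camera adjusted p = 1.45e-04, adjusted p = 0.115 with an estimated correlation). TP63 had a log2 fold change of -1.78. Of 18 classical subtype genes, 12 rose, 2 fell and 4 did not pass (13 and 2 adjusted over the list alone, camera adjusted p = 1.14e-05, adjusted p = 0.151 with an estimated correlation). TFF1 rose from 5.22 to 18.9. Of 16 NF-kB targets, 13 rose, 2 fell and 1 did not pass (13 and 2 adjusted over the list alone, camera adjusted p = 8.05e-05, adjusted p = 0.0677 with an estimated correlation). CXCL8 averaged 5.19. Of 19 mesenchymal genes, 13 rose, 4 fell and 2 did not pass (13 and 4 adjusted over the list alone, camera adjusted p = 0.00197, adjusted p = 0.0677 with an estimated correlation). The proteoglycan LUM rose from 2.16 to 23.2. LUM and COL1A1 (12.3 to 17.3, and 17.8 in shp16), 2 members that rose, are also the only fibroblast markers tested, and the rise of the mesenchymal list was not separated from RNA of other cells. VIM, at 13.3 to 17.9 in these libraries, was also raised in shNS replicate 2 (3.62) and shp16 replicate 3 (7.85), the libraries with plasma cell genes. Of 15 class I presentation genes, 11 rose, 0 fell and 4 did not pass (11 and 0 adjusted over the list alone, camera adjusted p = 3.79e-04, adjusted p = 0.254 with an estimated correlation).

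Of 40 mitosis genes, 1 rose, 25 fell and 14 did not pass (1 and 26 adjusted over the list alone, camera adjusted p = 3.79e-04, adjusted p = 0.405 with an estimated correlation). CENPF averaged 20.9. Of 44 DNA replication genes, 19 rose, 6 fell and 19 did not pass (19 and 6 adjusted over the list alone, camera adjusted p = 0.0177, adjusted p = 0.471 with an estimated correlation). ORC1 had a log2 fold change of 0.45 and E2F8 of 0.45. The replication call was also lost under quantile normalization (adjusted p = 0.0715, range 0.00116 to 0.471 over the alternatives). Of 11 replication-dependent histone genes, 1 rose, 7 fell and 3 did not pass (1 and 7 adjusted over the list alone, camera adjusted p = 0.0132, adjusted p = 0.186 with an estimated correlation), a class whose transcripts mostly lack poly(A) tails. Of 30 unfolded protein response genes, 18 rose, 4 fell and 8 did not pass (18 and 4 adjusted over the list alone, camera adjusted p = 4.16e-04, adjusted p = 0.129 with an estimated correlation). CHAC1 had a log2 fold change of 2.97. Of 25 heat shock and immediate early genes, 15 rose, 3 fell and 7 did not pass (15 and 3 adjusted over the list alone, camera adjusted p = 0.00179, adjusted p = 0.231 with an estimated correlation). Of 45 ribosomal protein genes, 32 rose, 1 fell and 12 did not pass (34 and 1 adjusted over the list alone, camera adjusted p = 1.92e-06, adjusted p = 0.550 with an estimated correlation). Of 22 YAP targets, 3 rose, 11 fell and 8 did not pass (3 and 13 adjusted over the list alone, camera adjusted p = 0.0276, adjusted p = 0.444 with an estimated correlation). With shNS replicate 2 and shp16 replicate 3 left out, a setting chosen after seeing the data, 5952 genes changed. That setting leaves the plasma cell genes in the co-silenced libraries. With the JCHAIN covariate, also chosen after seeing the data, 5463 genes changed, among them 4960 of the 6322 called in the main fit. JCHAIN was high in all co-silenced libraries, so the covariate can also take out part of the difference between groups.

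Against shp16, the largest falls and rises in the co-silenced libraries were in the following genes, named by the rule. TFF2, a gastric trefoil peptide, was 14.5 ± 2.26 in shp16 and 0.746 ± 0.140 in the co-silenced libraries, CEACAM5 53.8 ± 2.25 and 7.15 ± 0.143, and FXYD2, a sodium pump subunit, 10.3 ± 2.51 and 0.0710 ± 0.0750. The tumour antigen gene MAGEA3 (-2.70) and TCIM (-2.69) were lower too. HLA-DMB (2.64), LUM (2.52), EMP3 (2.71), CALCA (2.29) and CCN3 (2.21) were higher. CDKN2A itself was higher than in shp16 (0.58, limma adjusted p = 0.00124). In all, 2473 genes rose and 2906 fell among the 12506 tested (limma, Benjamini-Hochberg adjusted p under 0.05), of which 247 rose and 600 fell by at least 1.5-fold. The groups did not overlap in 47.4% of tested genes, where chance gives 10%. EMP3 was also above its group in the libraries with plasma cell genes, at 4.46 in shNS replicate 2 and 3.77 in shp16 replicate 3. With the JCHAIN covariate, chosen after seeing the data, 3763 genes changed against shp16, among them 3550 of the 5379 called in the main fit.

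Against the libraries labelled shp15, in which CDKN2B was not lower, the largest falls were of genes near zero elsewhere, RPL10L, TM4SF4, ACTG2, NRN1 and TUBA1A (log2 fold changes -6.79 to -5.27). ALPG was 23.2 ± 1.03 in those libraries and 292 ± 4.48 in the co-silenced ones, and the tumour antigen gene MAGEA1 0.0690 ± 0.0623 and 11.4 ± 0.611. JCHAIN (4.11), ITGB7 (3.70) and HLA-DMB (3.43) were higher as well, the first pair being plasma cell genes. CDKN2B was lower by a log2 fold change of -0.49 (limma adjusted p = 6.23e-05). In all, 3675 genes rose and 3404 fell among the 12506 tested (limma, Benjamini-Hochberg adjusted p under 0.05), of which 584 rose and 1095 fell by at least 1.5-fold. The groups did not overlap in 67.9% of tested genes, where chance gives 10%.

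In the 3 comparisons with shNS, 193 genes rose and 94 fell by at least 1.5-fold in all 3, with CDKN2B not lower in the libraries labelled shp15. S100A9, a calcium-binding protein of inflammation, rose from 9.14 in shNS to 83.4 in the libraries labelled shp15, 62.9 in shp16 and 49.3 in the co-silenced libraries, and LGALS1, a galectin, from 54.9 to 344, 206 and 232. Ranked by the smallest of the 3 changes, CES1, CGA and LXN came first among the rises and CALCA and CALCB among the falls. Across the tested genes, fold changes of shp16 and of the co-silenced libraries correlated at r = 0.772, against 0.398 for shp15 with shp16 and 0.356 for shp15 with co-silencing. Unchanged groups simulated against the same shNS libraries gave 0.503, 0.498 and 0.499. That level holds for groups without changes of their own and is no floor for r here. A value below it therefore does not mean less sharing than the controls alone give. Covariances exceeded the simulated ones, each near 0.0052, by 0.168, 0.101 and 0.0701. Of the genes that changed in both shp16 and co-silencing, 2180 rose in both, 2403 fell in both and 263 went opposite ways. The counts were 1611, 2305 and 710 for shp15 with shp16, and 1318, 1810 and 748 for shp15 with co-silencing. The same simulation gave on average 0.01 genes changed the same way for the first pair and 0 for each of the others. Its groups do not differ, so counts near 0 were fixed in advance and are no measure for these overlaps. Independent lists of the same sizes would give 866 rises, 1063 falls and 1918 opposite for shp16 with co-silencing. For shp15 with shp16 they would give 876, 1223 and 2076, and for shp15 with co-silencing 721, 1025 and 1723. Independence leaves out the shared shNS libraries. The 3 controls are too few to be divided between comparisons. Part of what is shared may come from a trait of the shNS line, which the simulated spread between libraries does not hold.

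Set against each other, the libraries labelled shp15 (CDKN2B not lower) and shp16 differed most in genes read at high levels in the former. RPL10L, TM4SF4, VIM, ACTG2 and ANXA2P3 were higher there (log2 fold changes 5.41 to 6.76). MUCL3 was 0.227 ± 0.0879 in the libraries labelled shp15 and 40.2 ± 8.01 in shp16, MUC5AC, a gastric mucin, 0.689 ± 0.134 and 28.5 ± 9.61, and RTN4RL2, ALPG and MAGEA1 were lower there too (-4.38, -4.17 and -4.15). In all, 3403 genes rose and 3882 fell among the 12506 tested (limma, Benjamini-Hochberg adjusted p under 0.05), of which 1018 rose and 871 fell by at least 1.5-fold. The groups did not overlap in 60.2% of tested genes, where chance gives 10%.

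The interaction asks whether co-silencing departed from the sum of the single changes, and it uses the libraries labelled shp15 although CDKN2B was not lower in them. A shift of the shNS line against all silenced groups alike also gives a departure, opposite in sign to the changes of those groups against shNS. NF-kB medians against shNS were 0.69 in the libraries labelled shp15, 1.28 in shp16 and 0.61 in co-silencing. Mitosis medians were -0.33, -0.37 and -0.21 in the same order. Such a shift was not told apart from changes that do not add. NF-kB targets lay below that sum in all 16 members (16 adjusted over all genes and over the list alone, camera adjusted p = 2.24e-08, adjusted p = 0.0206 with an estimated correlation). CXCL8 had a log2 departure of -2.99 and BIRC3 of -2.55. Of 20 ERK output genes 18 lay below (0 and 18 adjusted over the list alone above and below, camera adjusted p = 2.24e-08, adjusted p = 0.0122 with an estimated correlation). Of 25 cholesterol genes 22 did (1 and 22 adjusted over the list alone above and below, camera adjusted p = 2.35e-07, adjusted p = 0.0240 with an estimated correlation). MSMO1 had a log2 departure of -1.66. Above the sum lay 36 of 44 DNA replication genes (36 and 1 adjusted over the list alone above and below, camera adjusted p = 7.95e-07, adjusted p = 0.151 with an estimated correlation) and 31 of 40 mitosis genes (31 and 1 adjusted over the list alone above and below, camera adjusted p = 2.62e-07, adjusted p = 0.1999 with an estimated correlation). For 50 tested genes, CALCA (5.003 ± 0.15, SE) and SYT8 among them, the shNS level plus both single changes lies below 0 on the log2 scale of RPKM + 1, a level no library can have. A positive departure was then fixed by the scale, and 44 of these genes had one past the threshold. The largest negative ones were RPL10L (-6.82) and TM4SF4 (-6.78), which were near zero outside the libraries labelled shp15. JCHAIN (3.64, limma adjusted p = 0.0463), ITGB7 and IGLL5 passed narrowly, and each lost its call in 9 of the 12 fits without 1 library. Those left out shNS replicate 2 (adjusted p = 0.114, 0.121 and 0.107), shp16 replicate 1 or 2, any library labelled shp15 or any co-silenced library. Over all alternatives the adjusted p of JCHAIN lay between 7.65e-07 and 0.115. In all, 3578 genes departed upward and 3518 downward (limma, Benjamini-Hochberg adjusted p under 0.05), of which 1137 and 1833 by at least 1.5-fold.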

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

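Chosen only after the result was seen were the tests on another organism, on human cells of another type, on the split of shared reads, on protein-coding plasma cell genes, on a response to co-silencing, on a swap of libraries, on reads that hide a fall and on the interaction without a departure from the sum.

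Genes read in the libraries labelled shp15 and near zero in the other 9 included RPL10L, ACTG2 and NRN1, and the counts argue against lower depth as the cause, since 28 genes went from below 0.5 RPKM to above 5 RPKM in all 3 libraries, against 1 in shp16 and 0 in the co-silenced group. Of the 19 protein-coding ones, 15 share under 10% of their 31-base words with transcripts of other genes, more than the 5 allowed if reads were only divided between copies. Exact words miss copies with scattered differences, and the bound of 5 was set after the result. The count therefore does not decide against a division of reads between copies. Human cells of another type would match their own genes. Of tested pseudogenes, 27.0% rose at least 2-fold, against 1.40% in shp16 and 0.465% in co-silencing (Fisher's exact p = 5.78e-16 and 2.78e-18). These pseudogenes prompted the test, and some, such as ANXA2P3, passed the filter on low values only through the libraries labelled shp15. The shares therefore do not decide against human cells of another type. Reads from cells of another organism, aligned to the closest human copy, stay open: the odds ratio of pseudogenes among genes that rose at least 4-fold was 18.03 (95% interval 10.9 to 28.9), but these copies prompted the explanation, so the ratio does not support it. A change of the line itself stays open too, untested.

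Plasma cell genes stood in shNS replicate 2, shp16 replicate 3 and the co-silenced libraries, with ratios to JCHAIN that varied 1.03-fold for MZB1, 1.18-fold for ITGB7, 1.19-fold for IGLL5 and 1.43-fold for IRF4 and TNFRSF17 in these 5 while JCHAIN varied 3.67-fold. A response to co-silencing alone is argued against by JCHAIN at 20.4 RPKM in shp16 replicate 3. One source of plasma cell RNA or reads was first tested on all 49 genes read in shNS replicate 2 alone of the shNS libraries. The rule was set before its result, but it names JCHAIN and libraries already singled out by the pattern. The median ratio of shp16 replicate 3 to shNS replicate 2 over these genes was 0.995 (quartiles 0 to 2.21). That lies outside the range of 1.83 to 4.13 set around the ratio of JCHAIN, so the test missed its prediction. The range overlaps the quartiles, and the same selection gave 45 and 40 genes for shNS replicates 1 and 3, so most of the set may be scatter near the floor. Protein-coding genes were 19 of the set, JCHAIN included, against 1 and 3 in the selections for shNS replicates 1 and 3. Over the 18 protein-coding genes without JCHAIN, a restriction chosen because the first version failed, the median was 2.46 (quartiles 1.96 to 2.71), within that range. The 18 include ITGB7, IGLL5, IRF4 and TNFRSF17, whose values had prompted the test. Plasma cell RNA from separate sources could give such a ratio too, so it does not decide on a shared source. Carry-over between libraries and cells in the culture were not told apart.

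CDKN2B was not lower in the libraries labelled shp15. A swap with another group needs a library with CDKN2A at the level of shNS and less CDKN2B, and the lowest CDKN2B among libraries with CDKN2A above 20 RPKM was 3.71. Reads from another source that hide a fall cannot be told apart from no fall, since they would have to supply 35.9% of the CDKN2B signal to match the co-silenced libraries, and the share they supply is not known. A wrong label without a partner, silencing that acts on protein and silencing lost in culture were not tested.

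The interaction, a test of the difference itself, gave 7096 genes, and a shift of the shNS line alone counts as a departure in it too. Its named departures, of which those of CALCA and SYT8 were fixed in sign by the scale, were CALCA (5.003), JCHAIN (3.64), ITGB7 (3.20), SYT8 (2.61) and IGLL5 (2.61) upward, and RPL10L (-6.82), TM4SF4 (-6.78), ACTG2 (-5.82), NRN1 (-5.57) and TUBA1A (-5.44) downward. Lists that passed it, with their median log2 departures, were DNA replication (0.41), mitosis (0.50), interferon response (-0.50), class I presentation (-0.44), NF-kB targets (-1.33), TGF-beta response (-0.51), mesenchymal genes (-0.57), the classical subtype (-1.16), glycolysis (-0.41), cholesterol (-0.84), hypoxia (-0.77), ERK output (-0.99), ribosome biogenesis (0.41), ribosomal proteins (-0.18) and lysosome and autophagy (-0.20). With an estimated correlation the adjusted p was DNA replication (0.151), mitosis (0.1999), interferon response (0.115), class I presentation (0.439), TGF-beta response (0.129), mesenchymal genes (0.0933), the classical subtype (0.231), glycolysis (0.472), hypoxia (0.473), ribosome biogenesis (0.315), ribosomal proteins (0.772) and lysosome and autophagy (0.439). The ribosomal protein call was also lost with fry, under quantile normalization, without shNS replicate 1, without shp15 replicate 3, without shp16 replicate 2 and without shp15_shp16 replicate 1 (adjusted p = 0.132, 0.0627, 0.0581, 0.0693, 0.146 and 0.0846, range 0.00106 to 0.772 over the alternatives). The libraries labelled shp15, in which CDKN2B was not lower, and shp16 differed directly in 7285 genes, with RPL10L (6.76), TM4SF4 (6.49), VIM (6.41), ACTG2 (5.62) and ANXA2P3 (5.41) higher in the former, and MUCL3 (-5.05), RTN4RL2 (-4.38), ALPG (-4.17), MAGEA1 (-4.15) and MUC5AC (-4.07) lower.

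For the interaction, 1 of 100 random splits of the 12 libraries into groups, the real one included, gave as many genes (limma, 7096 against at most 92 in the others), and 8 of 100 gave at least its 15 lists (highest other 17). Other splits move the differences between groups into the spread, so these counts decide nothing about a departure from the sum. The 100 data sets were the real one and others with the single changes kept, no departure and the residuals shuffled over the libraries. Of these, 1, the real one, gave as many genes (at most 1 in the others) and 1 as many lists (at most 12, median 3). The gene count therefore lay far above what that spread alone gave. Since that spread alone called up to 12 lists, the list count does not tell which of the 15 lists depart. Pairs of groups allow 10 splits, too few for a share under 0.05. Every other split of a pair mixes its groups and moves their difference into the spread. Low gene counts in those splits were therefore fixed in advance and decide nothing about chance. In limma fits of the 6 libraries, the real splits gave 7862 genes for shp15 against shNS, 6740 for shp16, 7097 for co-silencing, 7838 for co-silencing against shp15, 3903 against shp16 and 6236 for shp15 against shp16, and the highest other gave 0 in each, with at most 110, 188, 367, 223, 1248 and 212 genes at an unadjusted p under 0.05. Lists numbered 14 (highest other 12), 17 (13) and 11 (8) against shNS in those fits.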

How the results depend on the processing

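The JCHAIN covariate, the omission of pseudogenes and the omission of shNS replicate 2 with shp16 replicate 3 were chosen after seeing the data. Requiring a mean of 5 RPKM left 7543 genes to test and so fewer calls: 4304 for shp15 against shNS, 4846 for shp16, 4139 for co-silencing, 4468 and 3517 for co-silencing against shp15 and shp16, 4582 for shp15 against shp16 and 4414 for the interaction, and it leaves CDKN2B without a value. The other settings kept these counts within 1.5-fold. CDKN2A in shp15 against shNS kept its direction and lost its call with a pseudocount of 0.1 (-0.31), no filter (-0.30), median-of-ratios scaling (-0.24), quantile normalization (-0.28) and the JCHAIN covariate (-0.29), and ranged from -0.37 to -0.22 with 1 library left out, and the cause was not tested. The interaction of ITGB7 turned to -0.0347 with the JCHAIN covariate, which removes what follows JCHAIN by construction, and JCHAIN itself has no value there. Lists passing in shp15, shp16 and co-silencing against shNS and in the interaction numbered 3, 1, 0 and 3 with an estimated correlation and 24, 27, 21 and 24 with fry, which asks another question. Correlations of fold changes moved to 0.352 (shp15 with shp16) and 0.309 (shp15 with co-silencing) with a pseudocount of 0.1, to 0.377 and 0.334 with quantile normalization, and the second to 0.354 to 0.370 without 1 shNS library, and the cause was not tested. Values that kept direction and call numbered 9528 for the named genes with a call and 686 for the 55 list calls, while 86 and 64 lost the call. For the 57 list tests without a call, 710 values stayed without and 52 gained one. Replicate numbers did not pair the libraries: 2 of 18 same-number pairs correlated above 0.1 (range -0.278 to 0.174), and a replicate block gave 6637, 7468, 6171, 6888, 5123, 7089 and 6889 genes in the order above, with the interactions of JCHAIN, ITGB7 and IGLL5 losing their calls. The interaction uses all groups, so it has no fit of only the groups compared. Depth limits genes near 1 RPKM, which rest on about 13.01 to 22.97 reads per kilobase.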

Other observations

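Some lists passed in none of the 3 comparisons with shNS nor in the interaction, although members moved both ways. Among CDK inhibitors, cyclins and RB family genes, CDKN1A, the inhibitor p21, rose from 7.53 ± 0.311 in shNS to 15.7 ± 0.483 in the libraries labelled shp15 (CDKN2B not lower), 15.6 ± 2.42 in shp16 and 13.4 ± 1.00 in the co-silenced libraries, and CDKN2C, the inhibitor p18, averaged 29.5 in shNS and 17.6, 14.9 and 25.0 in the same order. Against shNS, 9 rose and 14 fell of 27 of these genes in the libraries labelled shp15, 6 rose and 13 fell of 27 in shp16 and 12 rose and 8 fell of 27 in co-silencing (median log2 fold changes -0.20, -0.11 and 0.019, means 0.044, -0.21 and -0.064, which differ in sign in the libraries labelled shp15 and in co-silencing, camera adjusted p = 0.815, 0.156 and 0.931). In shp16, 6 rose and 11 fell of 25 p53 targets (camera adjusted p = 0.464), 13 rose and 11 fell of 29 junction genes (0.201), 14 rose and 10 fell of 27 integrin and invasion genes (0.276), 8 rose and 8 fell of 23 fatty acid genes (0.940, median -0.031 and mean 0.11) and 3 rose and 5 fell of 11 Wnt targets (0.309). CDH1, the epithelial cadherin, rose from 11.9 to 32.3, and MMP14, a membrane protease, fell from 22.6 to 10.1.

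Markers of other cell types were sparse. Of 5 tested hepatocyte markers, 2 rose in shp16 (AMBP to 16.4 and FGB to 4.27 from 7.16 and 1.92), and 4 fell in the libraries labelled shp15 while APOB, listed at 0 in shNS, stood at 3.498 (camera adjusted p = 0.0897 and 0.404, the latter with a median of -0.46 and a mean of 0.00399). REG1A, an acinar marker, was 7.77 in shNS, 3.42, 15.3 and 15.2 in the libraries labelled shp15, shp16 and co-silenced. RNR2, the mitochondrial 16S RNA, stood at 4480.3 to 4638 RPKM in the libraries labelled shp15 and 6718 to 7260.4 in shNS. It was also below shNS in shp16 (5262.6 to 5889) and in the co-silenced libraries (5903.6 to 6353.8). No endothelial marker passed the filter on low values, and no mitochondrially encoded mRNA was found under its listed symbol.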
